A study of Mus musculus with 2 samples.

How the data were processed

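RNA of splenic CD4+ T cells from DBA/1 and C57BL/6 mice was measured on 2 oligonucleotide arrays, 1 per strain, on day 7 after immunisation with glucose-6-phosphate isomerase (GPI). The cells were isolated by magnetic sorting, per the series' design text. Total RNA (3 µg per sample) was converted to biotin-labelled cRNA with an oligo(dT)-T7 primer, per the labels' protocols. Such priming samples the 3' end of transcripts. How many mice contributed to each RNA sample is not given in the sources used here.

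The deposited values are probe set intensities on a linear scale, 1 column per array, without detection calls. MAS5, the Affymetrix algorithm that summarises perfect-match and mismatch probes into a signal, is named in the submitters' processing notes. Its version and its scaling target are not given in the sources used here. The trimmed mean signal (2% left out at each end) was 145 for DBA/1 and 135 for C57BL/6, a ratio of 1.08, so the deposited intensities had not been brought to 1 common trimmed mean over all probe sets. Over probe sets above the floor on both arrays the median log2 ratio was 0.085, and over 18 bacterial hybridisation spike-in probe sets it was 0.087. Values were used as deposited, and this offset was removed in 3 alternatives.

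The table holds 22690 probe sets, of which 64 are controls. A platform annotation table gave exactly 1 gene symbol for 20380 of the other 22626, several for 691 and none for 1555. Entrez identifiers of 20351 probe sets matched a RefSeq gene table of assembly GRCm38.p6, whose symbols were identical. The genome build behind the array design is not given in the sources used here, so no coordinates are printed and the RefSeq table served only for names and gene order. Each of 12393 genes was represented by the probe set with the highest mean log2 signal. For 4956 genes more than 1 probe set was present.

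The comparison is the log2 ratio of the DBA/1 over the C57BL/6 intensity. MAS5 signals near background are unstable, so each array's median signal (37.6 for DBA/1 and 38.04 for C57BL/6) was used as a floor, and lower signals were set to it. A ratio with 1 side at the floor is therefore a bound and is written "at least N-fold". At least 1 signal lay over the floor for 6935 genes. A gene counted towards the numbers of differing genes only if its higher signal reached the 75th percentile of that array (171 for DBA/1 and 162 for C57BL/6), which 3919 genes did. With 1 array per strain there is no test, no p-value and no replicate error. Genes are named and counted by the size of the difference only, at 2-fold and 4-fold. The only internal repeat measurement is a second probe set of the same gene. Over 2321 genes with a pair of probe sets above the floor on both arrays, the SD of the difference between their log2 ratios was 0.43, which corresponds to an error of 0.31 per probe set. It covers probe error only, and not variation between mice, sorts or labelling reactions. The precision of every value is limited by the number of arrays.

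The gene lists, the rule for named genes and all alternatives except 1 were fixed before the data were examined. The 35 lists hold 702 entries, of which 599 had a probe set with 1 gene symbol. They cover T helper programmes, activation, surface receptors, cytokines, cell cycle, metabolism, interferon response, antigen presentation, quality indicators and markers of other spleen cells. A list's median log2 ratio over members above the floor on at least 1 array was ranked among 10000 random lists of the same size, matched on mean signal in 20 bins. A list was said to stand apart at or below percentile 2.5 or at or above percentile 97.5. This percentile describes these 2 arrays and is not a test across mice. Lists with fewer than 3 usable members received no median. Within lists, and within the gene families below, members at least 2-fold apart were counted without the minimum signal. Folds of list members such as Fcgr3, Itgae, Havcr2, Cd244a, Il1r2, Fasl, Ier3, Klrk1 and Tbx21 therefore rest on signals under the minimum. Many genes sit on more than 1 list.

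The rule for named genes takes the 15 genes with the largest ratio in each direction among counted genes, without clone or prediction names, the 4 members with the largest absolute ratio of each list, the 10 surface molecules with the largest ratio at or beyond 2-fold in each direction, and 24 chosen genes, of which 19 were measured under 1 symbol. Surface molecules were taken by the beginning of the gene symbol (receptor, integrin, CD and related families); "Sel" was read as selectins only, and intracellular binding partners and soluble antagonists with the same prefix were removed.

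Alternatives were median centring, quantile normalization, lowess on intensity (span 0.3), no floor, floors at percentiles 25 and 60, log2(signal + 32), minimum signals at percentiles 50 and 90, the mean over all probe sets of a gene, omission of probe sets whose suffix marks possible cross-hybridisation, and 3-fold in place of 2-fold. One more, leaving out genes of the other-cell lists, was added after the data were seen. On a simulated DBA/1 against C57BL/6 pair of 12393 genes with a log2 error of 0.3, 96 of 100 genes changed by 1.5 on the log2 scale and 100 of 100 changed by 2.5 were recovered, with 3 of 3622 unchanged genes called. The changed genes were drawn only from genes with a mean signal over 2 times the minimum signal. The simulated error was the same at every signal, without variation between mice, sorts or labelling reactions. These rates therefore check the calculation and do not give error rates for these arrays. Of 200 unchanged simulated lists, 11 stood apart, a share that the percentile limits set largely in advance. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.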

Results

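Splenic CD4+ T cells were compared between DBA/1 mice, which develop arthritis after immunisation with GPI, and C57BL/6 mice, which resist it. The series asked which molecules are highly expressed on the CD4+ T cells of the susceptible strain. Both samples were taken on day 7 and hybridised to 1 array each. The median signal was 37.6 for DBA/1 and 38.04 for C57BL/6, and the highest signals were 9719 for DBA/1 and 8931 for C57BL/6. The 3' over 5' signal ratio of the Actb control was 1.25 in DBA/1 and 1.27 in C57BL/6, that of the Gapdh control was 0.781 and 0.709, and that of the Tfrc control was 5.08 and 4.15. Actb itself read 6627 and 6504. The Gapdh control probe sets were 0.28 to 0.45 higher in DBA/1 on the log2 scale, as deposited. The 27 Bacillus control probe sets stayed at or below 6.89.

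Of the 15 named genes with the largest ratios in each direction, those higher in DBA/1 included phagocyte genes and H2-Ea, and those higher in C57BL/6 included Mndal, 2 Trim genes, H2-Eb1 and 2 inducible heat shock genes. Fpr2, a formyl peptide receptor of phagocytes, read 668 in DBA/1 and 42.8 in C57BL/6, a 15.6-fold difference. Serpinb1a, an inhibitor of neutrophil elastase, was 11.97-fold higher, Hp (haptoglobin) 9.25-fold, Anxa1 (annexin A1) 7.33-fold, the neutrophil surface protein Cd177 7.14-fold and Lcn2 (lipocalin 2) 6.53-fold. Cap1, a regulator of actin filaments, was 9.38-fold higher, with 2 probe sets at log2 ratios of 3.23 and 3.22, and Hebp1 was 7.34-fold higher. For 7 further genes of this group the C57BL/6 signal lay under the floor: H2-Ea was at least 11.7-fold higher in DBA/1, Tmem87a at least 10.8-fold, Mlycd at least 10.02-fold, Stab2 at least 9.60-fold, Ifi202b at least 9.204-fold, Scg5 at least 8.43-fold and Slfn4 at least 8.18-fold.

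In the other direction, Mndal, of the interferon-inducible Ifi200 family, read 16.5 in DBA/1 and 2039 in C57BL/6 and was at least 54.3-fold higher in C57BL/6. Trim12a was at least 15.4-fold higher there, Klk1 (kallikrein 1) at least 12.9-fold, Pdk1 (pyruvate dehydrogenase kinase 1) at least 12.7-fold, Trim34a at least 11.6-fold, Cd8b1 (CD8 beta chain) at least 5.30-fold and Ttc27 at least 4.91-fold. H2-Eb1, an MHC class II beta chain, was 12.5-fold higher in C57BL/6. The inducible HSP70 genes Hspa1a and Hspa1b were 9.004-fold and 6.85-fold higher, and the 3 probe sets of Hspa1b lay at log2 ratios of -2.78, -2.84 and -3.03. Rpgrip1 was 6.99-fold higher in C57BL/6, Gbp7 6.35-fold, Apobec3 4.63-fold, Donson 4.53-fold and Tlr1 (toll-like receptor 1) 4.29-fold.

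**Figure D1:**
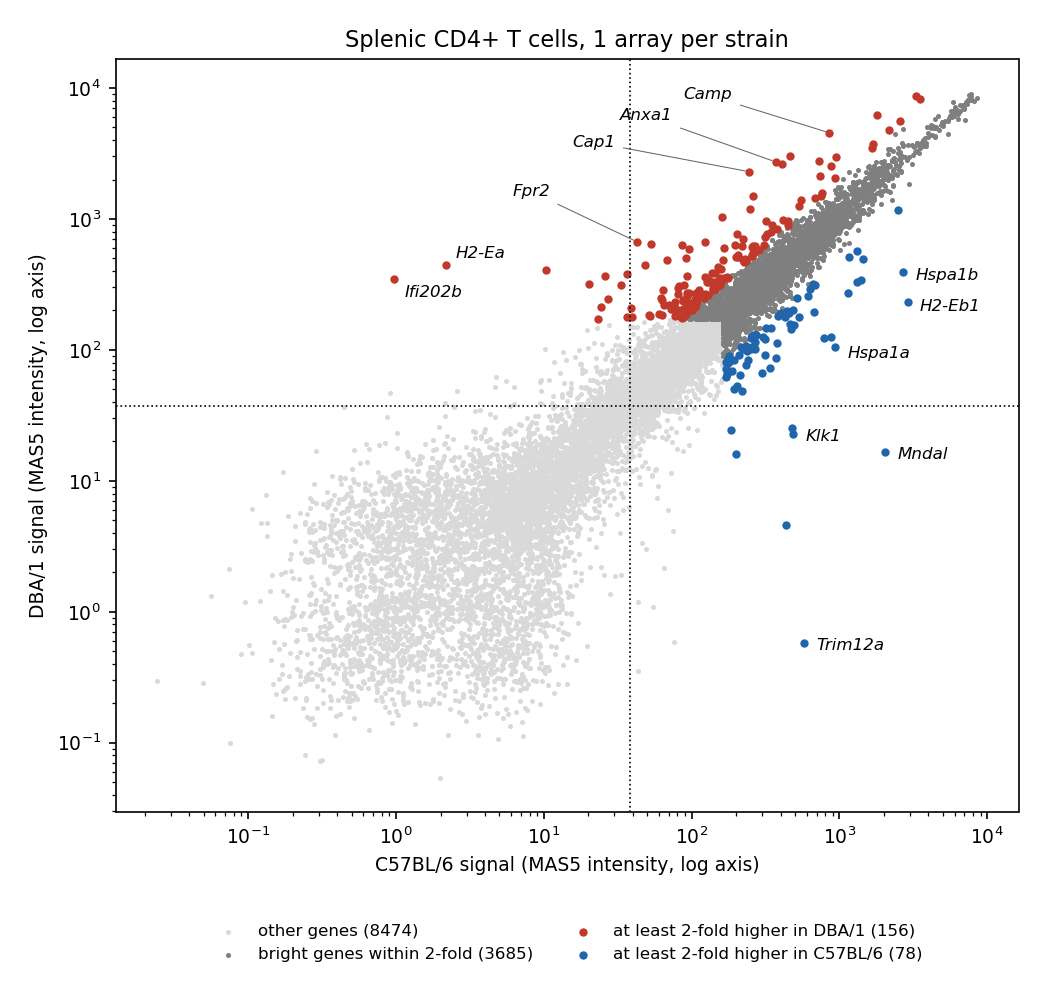
DBA/1 signal (vertical, log axis) against C57BL/6 signal (horizontal, log axis) for 12393 genes, 1 point per gene and 1 array per strain, with dotted lines at the floors of 37.6 and 38.04. Red points are the 156 genes at least 2-fold higher in DBA/1 and blue points the 78 at least 2-fold higher in C57BL/6; Mndal and Trim12a lie under the DBA/1 floor, and H2-Ea and Ifi202b under the C57BL/6 floor.

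Of the 3919 counted genes, 156 were at least 2-fold higher in DBA/1 and 78 at least 2-fold higher in C57BL/6. Scaling moved this split: it was 122 and 95 after median centring, 117 and 92 after quantile normalization and 116 and 92 after lowess. At 4-fold the numbers were 30 and 18. The log2 signals of the counted genes correlated across genes with r = 0.868; genes are not independent replicates. Among 83 of the differing genes with a second usable probe set, it pointed the same way for 77 and was itself beyond 2-fold for 40. The second probe set of Trim30a gave a smaller difference (log2 ratio -0.45 against -2.03). Those of Serpinb1a and Rpgrip1 had 1 side under the floor, so their size could not be compared. There was 1 array per strain, so differences between mice of 1 strain were not measured and no gene carries a test.

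Genes of the T cell receptor and its signalling had a small median difference between the sorted samples, and lists of several other spleen cell types had larger median differences. Cd4 read 913 in DBA/1 and 857 in C57BL/6, and Cd3e 747 and 791. The 18 T cell receptor and signalling genes had a median log2 ratio of -0.041, with none beyond 2-fold in the probe set used, at percentile 0.85 of random lists, whose median was 0.15. The list thus stood apart as lower in DBA/1, and its median was -0.13 after median centring, -0.20 after lowess and -0.21 after quantile normalization. The largest were Zap70 (-0.67), Thy1 (-0.54) and Cd247 (-0.24), lower in DBA/1, and Trat1 (0.38), higher. Another probe set of Cd247 lay at -1.13.

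All 16 usable neutrophil genes were higher in DBA/1, 15 of them at least 2-fold, with a median log2 ratio of 1.53 (2.89-fold) that exceeded all 10000 random lists. The granule genes Ltf (lactoferrin) and Camp (cathelicidin) were 6.43-fold and 5.32-fold higher. Camp was far over the floor on both arrays and read 4546 in DBA/1 and 854 in C57BL/6. The monocyte and macrophage list had a median of 0.81, with 19 of 21 members higher and 8 at least 2-fold. Hmox1 (heme oxygenase 1) was 3.41-fold higher, the Fc receptor Fcgr3 3.31-fold, Lyz2 (lysozyme) 3.14-fold and the iron exporter Slc40a1 2.62-fold. Fcgr3 was under the minimum signal on both arrays, at 133 in DBA/1 and, near the floor, 40.3 in C57BL/6. The B cell list had a median of 0.94, with 7 of 14 members at least 2-fold higher, among them Cd22 (2.47-fold), Cr2 (2.25-fold), Cd79a (2.05-fold) and Blk (at least 2.85-fold). Cr2, Cd79a and Blk were under the minimum signal on both arrays. Another 2 B cell genes were at least 2-fold lower, including Cd72 (log2 ratio -1.70, also under the minimum signal). The mean of the B cell list was 0.48, with 4 of 14 members lower in DBA/1. Ighm, named after its value was seen, read 3304 in DBA/1 and 3326 in C57BL/6. The B cell median was 0.59 with the floor at percentile 60 and 0.34 with log2(signal + 32). The dendritic cell list had a median of 0.79, with Fscn1 3.25-fold, Cst3 2.90-fold and Cd209a 2.58-fold higher; with log2(signal + 32) it was 0.28. Its mean was 0.43, because 4 of its 10 members were lower in DBA/1, namely Ccr9 (-1.26), Bst2 (-0.74), Tcf4 (-0.55) and Irf8 (-0.33), the last 3 named after their values were seen.

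CD8 T cell genes went the other way. All 6 usable members were lower in DBA/1, with a median log2 ratio of -1.01, below all 10000 random lists. Nkg7 was 3.80-fold, Klrk1 2.08-fold and Ctsw 1.96-fold higher in C57BL/6, while Cd8a itself was near the floor at 52.9 and 78.0. The NK cell list had a median of 0.086 over 6 members and a mean of -0.18, with Gzmb and Tyrobp higher in DBA/1 (log2 ratios 0.91 and 0.83) and Klrd1 and Il2rb lower; its direction depended on the floor. Plasma cell genes (0.43, 5 members, led by Irf4 at 0.86 and Jchain at 0.84, with Prdm1 at 0.43 and Xbp1 at 0.21), erythroid genes (-0.14, 9 members, mean 0.016, with Car1 at 0.91 and Hbb-b2 at -0.74) and platelet genes (0.37, 3 members, with Ppbp at 0.42 and Pf4 at 0.37) lay within the range of random lists. Of the mast cell, basophil and eosinophil list only Hdc was above the floor (at least 1.82-fold higher in DBA/1), and of the stroma list only Pecam1 (1.13-fold). The Y-linked genes Eif2s3y, Uty and Kdm5d were above the floor on both arrays, with log2 ratios of 0.90, 0.20 and -0.16; the median of the sex-linked list was 0.20.

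**Figure D2:**
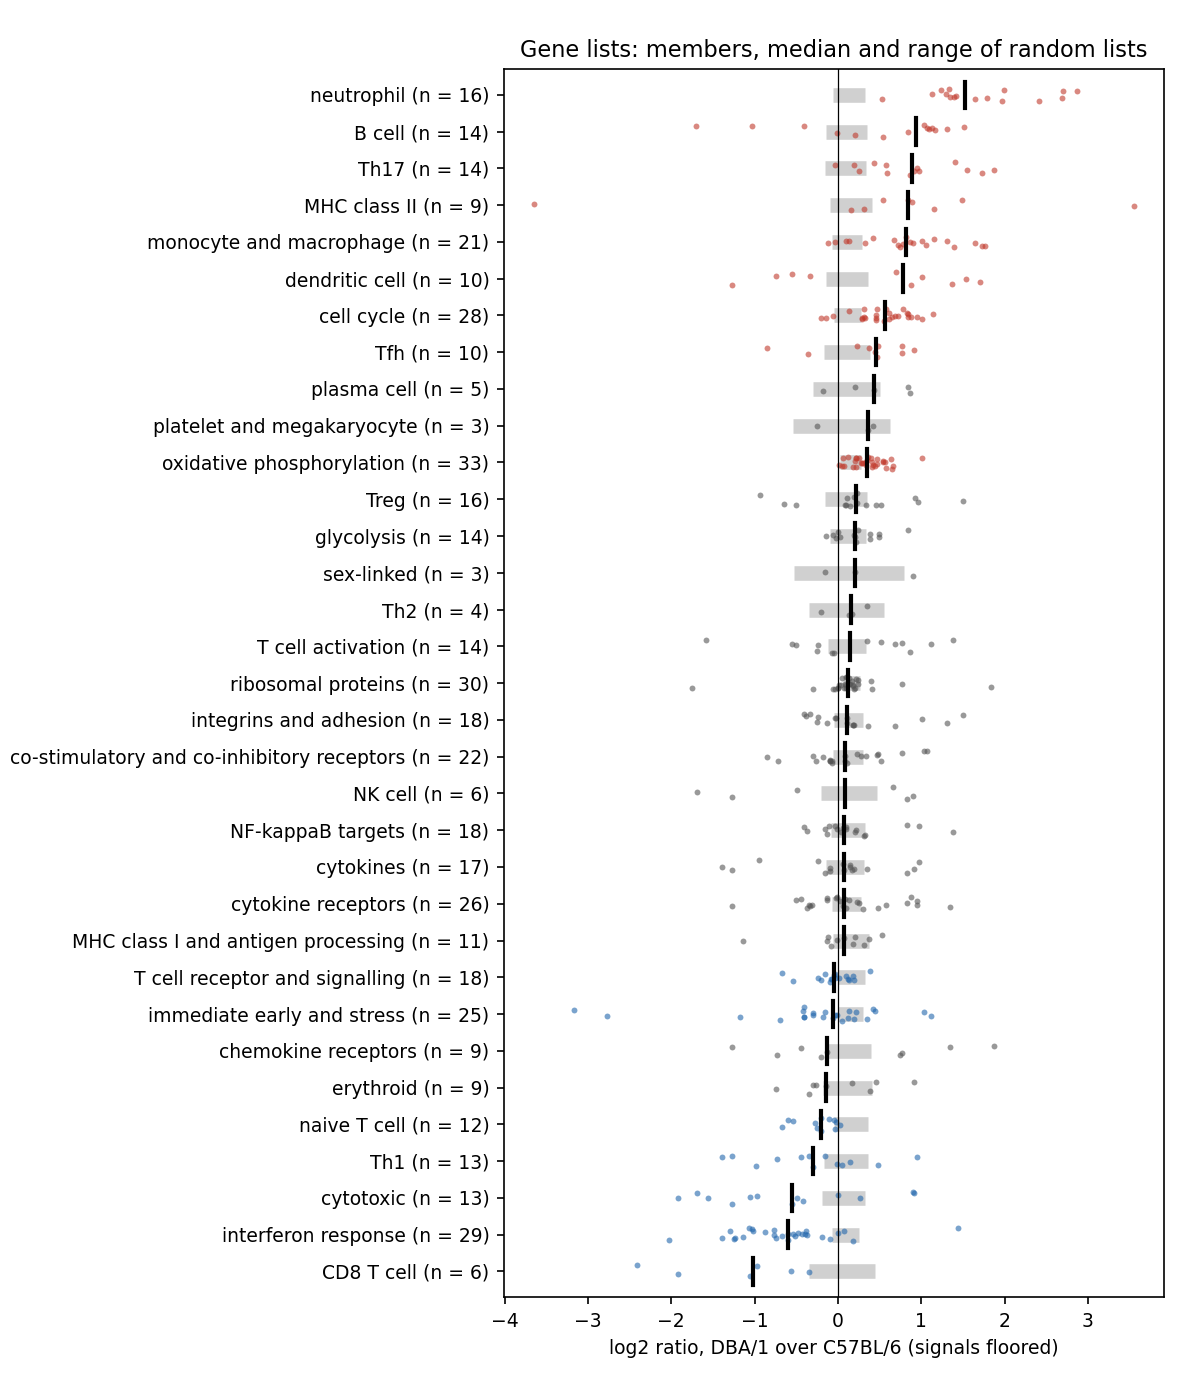
Log2 ratio of DBA/1 over C57BL/6 (horizontal) for the members of 33 gene lists (points), their median (black bar) and the central 95% range of medians of 10000 random lists matched on signal (grey bar); n is the number of members above the floor. Red lists (9) lie above and blue lists (7) below that range, from neutrophil genes at 1.53 to CD8 T cell genes at -1.01.

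Among T helper programmes, Th17-associated genes were higher and Th1-associated genes lower in DBA/1. The Th17 list had a median log2 ratio of 0.89 over 14 members, above all 10000 random lists, with 13 members higher and 4 at least 2-fold. These were the chemokine receptor Ccr6 (605 against 165, 3.67-fold), the aryl hydrocarbon receptor Ahr (269 against 81.2, 3.32-fold), Tmem176a (482 against 164, 2.94-fold, with a second probe set at a log2 ratio of 1.11) and Ltb4r1 (at least 2.64-fold). The cytokine Il17a read 43.5 in DBA/1 and was under the floor in C57BL/6, at least 1.14-fold. Of its 14 members 6 also sit on other lists, and B cell and myeloid lists moved in the same direction by similar or larger amounts (medians 0.94 and 0.81).

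The Th1 list had a median of -0.30 over 13 members, at percentile 0.19. Ifng (interferon gamma) was 2.62-fold, the chemokine Ccl5 2.41-fold and the transcription factor Tbx21 1.97-fold higher in C57BL/6, and the interleukin 18 receptor Il18r1 was 1.93-fold higher in DBA/1. The Th1 list no longer stood apart without a floor or with the floor at percentile 25 (median -0.16 in both cases) or with log2(signal + 32) (-0.093). CD8 T cell genes, which include Nkg7 and Ctsw, were lower in DBA/1 beside it. Th2 genes had a median of 0.15 over 4 usable members, with Gata3 at -0.20, Il4 at 0.35, Stat6 at 0.18 and Il4ra at 0.13. Regulatory T cell genes had a median of 0.21 over 16 members, at percentile 82.05. Foxp3 was 98.02 and 91.2, Ctla4 556 and 441 and Il2ra 56.4 and 80.1. Il10 was under the floor on both arrays. The integrin Itgae was 2.82-fold higher in DBA/1, Ebi3 1.95-fold and Fgl2 1.89-fold, and Plagl1 at least 1.92-fold lower. Itgae was under the minimum signal on both arrays, at 123 in DBA/1 and, near the floor, 43.6 in C57BL/6. Follicular helper genes had a median of 0.46 over 10 members, at percentile 99.2, with no member beyond 2-fold. The B cell list, at 0.94, was displaced the same way, and B cells also express Cxcr5, Bcl6 and Pou2af1. Cxcr5 was 1.71-fold and Icos 1.70-fold higher, Il21 at least 1.89-fold higher and Bcl6 1.36-fold higher in DBA/1, while Cd200 was lower (log2 ratio -0.85).

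**Figure D3:**
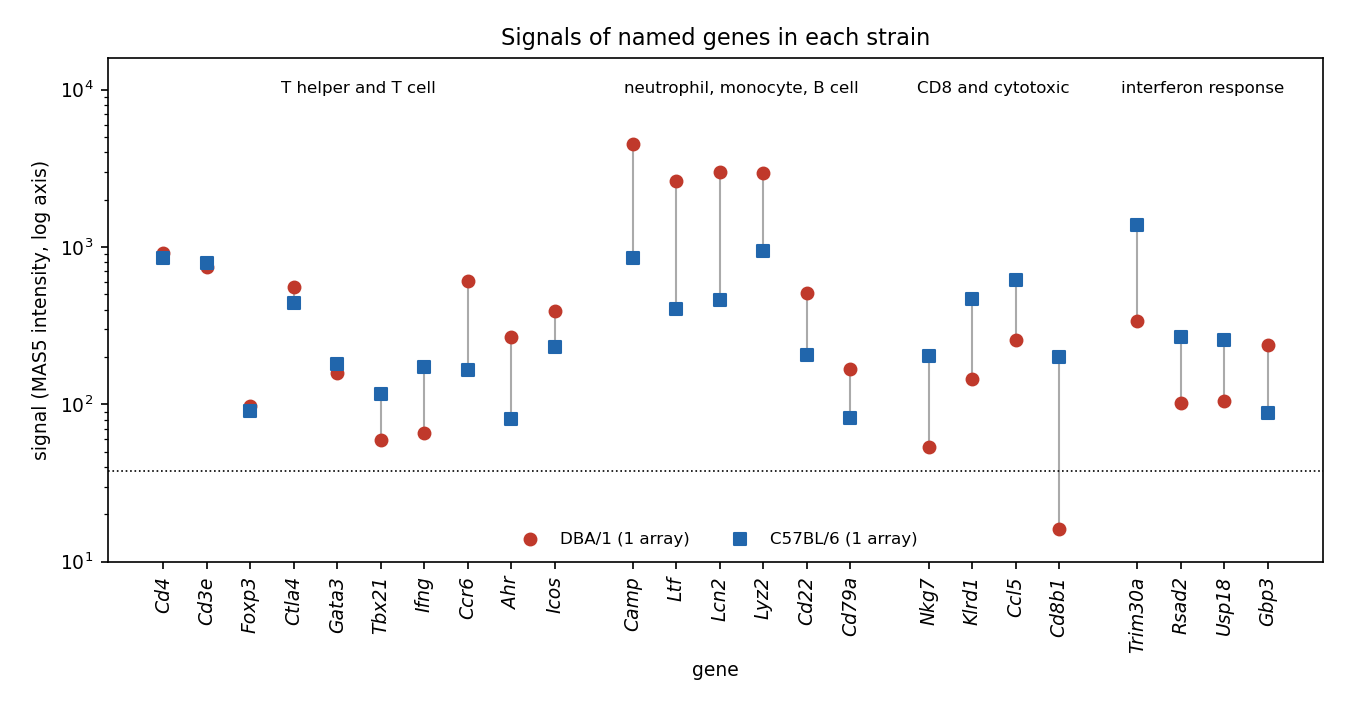
Signal (vertical, log axis) of 24 named genes in DBA/1 (red circles) and C57BL/6 (blue squares), 1 array each, in 4 groups; the dotted line is the DBA/1 floor of 37.6. Cd4, Cd3e and Foxp3 nearly coincide, Ccr6 and Ahr lie higher in DBA/1 with the neutrophil, monocyte and B cell genes, and Ifng, Tbx21 and the cytotoxic genes lie higher in C57BL/6.

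The naive T cell list had a median of -0.20 over 12 members, 11 of them lower in DBA/1, at percentile 0.04, and the median reached -0.355 after quantile normalization. Neutrophil, B cell and monocyte lists were higher in DBA/1 in the same samples (medians 1.53, 0.94 and 0.81). S1pr1 was 1.59-fold, Bach2 1.52-fold, Lef1 1.45-fold and Satb1 1.21-fold higher in C57BL/6. The T cell activation list had a median of 0.15 over 14 members, within the range of random lists, and its members went both ways. Over the alternatives the median of the activation list ranged from -0.048 to 0.35. Cd83 was 2.60-fold and Ier3 2.17-fold higher in DBA/1, Irf4 1.82-fold higher, and the phosphatase Dusp2 2.99-fold higher in C57BL/6. Cd44 read 692 and 814. NF-kappaB targets had a median of 0.078, with Ccl3 at 0.98, Tnf at 0.84 and Junb at -0.40. The list of immediate early and stress genes had a median of -0.062 and a mean of -0.26, at percentile 0.24; the median was -0.15 after median centring, -0.23 after lowess and -0.25 after quantile normalization. Apart from Hspa1a and Hspa1b, the co-chaperone gene Dnajb1 was 2.25-fold higher in C57BL/6. Of the same list, Ier3 and Atf3 were 2.17-fold and 2.05-fold higher in DBA/1, Atf3 being named after its value was seen.

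Of 114 counted surface molecules, 16 were at least 2-fold higher in DBA/1 and 5 at least 2-fold higher in C57BL/6. After Cd177, the largest in DBA/1 were Ccr6 (3.67-fold), the Fc receptor Fcgrt (3.65-fold), the semaphorin receptor Plxnb2 (3.60-fold), Ccrl2 (2.77-fold), Cd83 (2.60-fold), the lectin Cd209a (2.58-fold), the B cell receptor regulator Cd22 (2.47-fold), Cd7 (2.39-fold) and Cd300a (2.30-fold). Cd7 read 771 in DBA/1 and 323 in C57BL/6. The 5 higher in C57BL/6 were Cd8b1, Tlr1, Klrd1 (3.24-fold), Il2rb (2.41-fold, with a second probe set at a log2 ratio of -0.46) and Ccr9 (2.40-fold, with a second probe set at -1.42). Without the genes of the other-cell lists 12 and 1 remained, against neutrophil and B cell medians of 1.53 and 0.94. Those 12 are not free of genes of other cells. Cd177, a neutrophil surface protein, is on none of the lists and stays among them.

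The co-stimulatory and co-inhibitory receptors as a list had a median of 0.090 over 22 members, with Havcr2 2.09-fold and Cd244a 2.04-fold higher in DBA/1. Chemokine receptors had a median of -0.13 and a mean of 0.22 over 9 members; Ccr1 was at least 2.54-fold higher in DBA/1. Cytokines had a median of 0.075 and a mean of -0.019, with Xcl1 at least 1.93-fold lower in DBA/1. Cytokine receptors had a median of 0.071, with Il1r2 2.55-fold and Il1r1 at least 1.94-fold higher in DBA/1. Integrins and adhesion molecules had a median of 0.11, with the myeloid integrins Itgam (at least 2.47-fold) and Itgax (2.01-fold) and Itgb1 (1.61-fold) higher in DBA/1. These 5 lists lay within the range of random lists, and the sign of all their medians changed under at least 1 alternative.

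Interferon response genes were lower in DBA/1. The list had a median log2 ratio of -0.60, below all 10000 random lists, with 26 of 29 members lower, 9 of them at least 2-fold, and 1 at least 2-fold higher. Trim30a was 4.09-fold, the antiviral gene Rsad2 (viperin) 2.62-fold and the deubiquitinase Usp18 2.46-fold higher in C57BL/6, and all 3 probe sets of Rsad2 were lower in DBA/1. Gbp3 was the member at least 2-fold higher in DBA/1 (2.71-fold). Isg20 and Ifi35, named after their values were seen, were slightly higher there (log2 ratios 0.18 and 0.072). The cytotoxic list had a median of -0.55 over 13 members, with 5 at least 2-fold lower in DBA/1. Its median was -1.27 without a floor or with the floor at percentile 25, and -0.42 without the genes of the other-cell lists, a choice made after the data were seen. The CD8 T cell list, which shares genes with it, was also lower at -1.01. Besides Nkg7 and Ccl5, the cytotoxic genes at least 2-fold lower in DBA/1 included Klrd1 (3.24-fold) and Fasl (2.96-fold). In the other direction, 3 of the 13 were higher in DBA/1. They included Gzmb and Klrg1 (log2 ratios 0.91 and 0.92), Klrg1 being named after its value was seen. The cytotoxic list shares 7 of its usable genes with other lists.

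MHC class II genes had a median of 0.84 over 9 members, above all 10000 random lists, with 8 members higher and 3 at least 2-fold. They moved with the B cell, dendritic cell and macrophage lists, whose medians were 0.94, 0.79 and 0.81. The transactivator Ciita was 2.81-fold and H2-Oa 2.23-fold higher in DBA/1. H2-Ea and H2-Eb1, whose products pair in the I-E molecule, differed in opposite directions. C57BL/6 mice carry a deletion in H2-Ea, and its signal there was 2.17. H2-Eb1 has only 1 probe set, which read 230 in DBA/1 and 2887 in C57BL/6. Whether a strain variant under that probe set gave its difference was not tested. MHC class I and antigen processing genes had a median of 0.068, with B2m at 0.068 and H2-M3 at 0.53. The median of this class I list ranged from -0.10 to 0.31 over the alternatives. H2-T24 read 68.4 and 52.9, Psmb9 lay at 0.31, and the peptide transporter Tap1 was 2.20-fold higher in C57BL/6.

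Cell cycle genes were higher in DBA/1, with a median of 0.57 over 28 members, above all 10000 random lists, and 25 members higher. The neutrophil list, which includes the granulocyte precursor genes Mpo (1.35), Elane (1.29) and Prtn3 (1.99), named after their values were seen, was displaced the same way at 1.53. Cdk1 was 2.20-fold, Cdc20 2.02-fold, Prc1 1.92-fold and Nusap1 1.83-fold higher. On the deposited scale all 33 oxidative phosphorylation genes had log2 ratios above 0, with a median of 0.35 (percentile 99.8) and Ndufa4 2.01-fold, Ndufs1 1.58-fold, Cox7a2 1.57-fold and Sdhd 1.56-fold higher; the median was 0.19 after quantile normalization. Glycolysis genes had a median of 0.21, with Hk2 at 0.84 and Slc2a3 at 0.49, and ribosomal protein genes one of 0.12, both within the range of random lists. The ribosomal protein genes with the largest ratios were Rpl14 (log2 ratio 1.83), Rps6 (-1.75) and Rps27 (0.77). Their probe sets were dim for this list. Rpl14 read 316 in DBA/1 and 88.6 in C57BL/6, Rps6 113 and 380, and Rps27 459 and 268, while Rpl11 read 6162 and 4646.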

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

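The comparison in this part was chosen after the results were seen. Probe sets with no gene symbol or several were left out of the comparisons above. Of 620 bright enough to be counted, 50 differed at least 2-fold between the strains, 27 higher in DBA/1 and 23 higher in C57BL/6, or 8.06% against 6.16% of the probe sets with 1 gene. They were noticed because the comparisons above do not use them, although some share a gene with a probe set that was used. Several belong to MHC class I and Ifi200 families: a probe set for H2-Q5 and H2-K1 was at least 25.7-fold higher in DBA/1, one for Ifi203 and its pseudogene at least 24.1-fold higher in C57BL/6, and one for H2-Q6 and H2-Q8 lay at a log2 ratio of -1.95. No explanation was tested for these probe sets.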

How the results depend on the processing

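The alternative that leaves out genes of the other-cell lists was chosen after the results were seen. Of the 16 lists that stood apart, 15 did so in the same direction under every alternative run for lists. The exception was Th1, with medians of -0.16 (floor at percentile 25, and no floor) and -0.093 with log2(signal + 32). Lists that stood apart only under an alternative were NK cell (-0.32 and -0.57 with the floor at percentile 25 or absent, 0.67 with the floor at percentile 60 or without cross-hybridising probe sets), T cell activation (0.35, floor at percentile 60), chemokine receptors (-0.13, floor at percentile 60), erythroid (-0.20 at percentile 25, -0.27 without a floor, -0.12 with log2(signal + 32)) and plasma cell (0.44 with lowess, 0.45 with quantile normalization, 0.64 without cross-hybridising probe sets). The cause was not tested. Median centring shifts all ratios alike, so it cannot change a list's percentile and is no check on whether a list stands apart.

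The numbers of genes higher in DBA/1 and in C57BL/6 followed the threshold by construction: 50 and 28 at 3-fold, 266 and 132 with a minimum signal at percentile 50, 63 and 30 with one at percentile 90. At 4-fold they were 15 in DBA/1 at percentile 90 and 11 in C57BL/6 with log2(signal + 32), which shrinks ratios of low signals. Leaving out genes of the other-cell lists gave 130 and 72. Surface molecules higher in DBA/1 numbered 34 and 7 with minimum signals at percentiles 50 and 90 and 9 with log2(signal + 32); those higher in C57BL/6 numbered 2 at percentile 90, 3 without cross-hybridising probe sets and 1 without the other-cell genes. The probe set error was 1.03 without a floor, against 0.31. Removing the offset of 0.085 gave a more even split: 122 against 95 after median centring, 117 against 92 after quantile normalization and 116 against 92 after lowess. Of 1688 values of named genes under alternatives, 1521 moved by less than the probe set error, 167 by more, and 0 of the differences at or beyond 2-fold changed sign. Part of the 1521 was fixed in advance. Minimum signals at percentiles 50 and 90 leave every ratio unchanged, and median centring moves each by only 0.085. A changed floor cannot move genes that stay above it on both arrays. Signals below the floor have no order here. No paired analysis was possible because each strain has 1 array, and for the same reason no replicate could be left out.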

Other observations

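The tests in this part were chosen after the results were seen, with an exception. The count of neighbouring genes over both directions was set out before its result, without a prediction for each direction. Gene families (11 of them) were taken by symbol after the data were seen. Mitochondrial ribosomal proteins were higher in DBA/1 (median log2 ratio 0.29, 63 of 74 genes, percentile 99.9 of random lists), as were proteasome subunits (0.31, 33 of 38, percentile 99.4), none of them beyond 2-fold. S100 proteins (median 1.19, 5 of 6 at least 2-fold) and annexins (1.24, 4 of 7) were also higher, and S100a8, S100a9 and Anxa1 among them are on the neutrophil list, whose median was 1.53. Zinc finger genes named Zfp were lower (-0.16, 55 of 91 lower). The directions of these 5 families held under median centring, quantile normalization and lowess, with mitochondrial ribosomal medians of 0.20, 0.18 and 0.18 and proteasome medians of 0.22, 0.17 and 0.16. Guanylate-binding proteins were lower in DBA/1, with a median of -1.03 below all random lists and -1.12 under each of the 3 scalings; 4 of 5 were lower, 3 of them at least 2-fold, and Gbp3 was higher. Among 45 heat shock and DnaJ genes the median was 0.021, negative under the 3 scalings and within the range of random lists, while Hspa1a, Hspa1b, Dnajb1, Dnajb4 and Hsph1 were at least 2-fold higher in C57BL/6, the last 3 at log2 ratios of -1.17, -1.17 and -1.14. Galectins stood apart as lower by their median (-0.31, percentile 0.43), but their mean was 0.30, and the 2 members beyond 2-fold, Lgals3 (2.52) and Lgals1 (1.11), were higher in DBA/1. Cathepsins (0.33), tubulins (0.057) and chaperonin subunits (0.041) lay within the range of random lists, and the latter pair turned negative under the 3 scalings.

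The neutrophil genes were the most displaced list. Array scaling is argued against, because the T cell receptor and signalling list had a median log2 ratio of -0.041 on the same arrays, against 1.53 for neutrophil genes. More neutrophil RNA in the DBA/1 sample stays open: 15 of 16 members were at least 2-fold higher, but that count prompted the explanation and is no independent test of it. Camp read 4546 and 854 and Ltf 2610 and 406, although sorting for CD4 should remove these cells. A difference between the spleens of the 2 strains and one between the magnetic sorts cannot be separated with 1 sort per strain. Monocyte, B cell and class II genes were displaced the same way, and CD8 genes the opposite way, so the sorted samples may differ in more than 1 cell type.

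The higher Th17 list may reflect T cells or RNA of carried-over B cells and myeloid cells, which are known to express Ccr6, Ahr and Tmem176a. These cannot be told apart here: of 4 members that such cells hardly express (Il17a, Il21, Il17re and Rora), only 1, Rora, had both signals over 2 times the floor. Their median log2 ratio was 0.59.

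Several of the largest differences lie in families known to vary between inbred strains. A variant under a single probe set is argued against as the cause for the 8 genes at least 4-fold lower in DBA/1 that have a second usable probe set: the median of the second probe sets was -2.98, and 6 of the 8 were again beyond 2-fold. That of Trim30a was not, and that of Rpgrip1 was under the floor in DBA/1 and gives only a bound. Genes with only 1 usable probe set stay open, as do haplotypes that alter every probe set of a gene. Where 2 probe sets of a gene share sequence, 1 variant could alter both, and probe positions were not compared. If local haplotypes contributed, differing genes could cluster: 123 of 233 had another differing gene among the 5 nearest counted genes on either side, against a median of 107 (95% range 89 to 125) for random sets, which leaves it open. For the genes higher in C57BL/6 alone it was 28 of 77 against 14 (6 to 23), and for those higher in DBA/1 63 of 156 against 52 (38 to 67), within the random range. The former include the neighbours Trim34a, Trim12a and Trim30a, and Hspa1a and Hspa1b; related genes that are regulated together would give the same.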
